A study of Mus musculus with 36 samples.

How the data were processed

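Gene expression was measured on 36 Illumina bead arrays of total RNA from macrophages grown out of mouse bone marrow with M-CSF. Per the labels, the mice were wild type (wt) or lacked both liver X receptors, LXRα and LXRβ (double knockout, dko), were of the C57BL/6 strain and were 2 to 5 months old. Cells were loaded with cholesterol crystals for 3 h or left without them. After the excess crystals had been washed away, cells received 10 mM cyclodextrin (CD), a cyclic sugar that carries cholesterol in its cavity, for 4 h or were left without it. The 8 groups held 5 arrays each for wt and 4 each for dko. The labels number the wt arrays of a group 1 to 5 and the dko arrays 6 to 9, and do not say whether a number stands for an animal, a culture or a day. The p-values therefore measure the spread between these arrays, which may in part be technical.

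Per the labels' protocols, RNA was isolated with TRIzol, and biotin-labelled cRNA was prepared with a linear amplification kit. The authors deposited a table of intensity values with a detection p-value for each probe and array. This intensity had been neither normalized between arrays nor background-subtracted as far as the values show, since array medians ran from 83.5 to 128 and no value lay below 69.4. The detection p-value of each probe on each array was deposited beside its intensity, and the export settings of the scanner are not given in the sources used here. The deposited series matrix, per its values, held log2 of the same intensity, with a largest difference of 5.57e-05 over all probes and arrays, so its scale, centring and direction are known and it carried no further normalization. Its array medians ran from 6.38 to 7.00. The submitters' processing notes name Partek, with neither a role nor a version.

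The table held 45281 probes, and 1 line without a probe name was left out. Gene symbols came from the array table and were updated through a table of RefSeq gene names. By symbol 27743 probes matched, by synonym 7998 matched, and 9540 kept the file's own name. In 27 cases a match was refused because it lay on another chromosome than the array table gives. Of the probes that passed the filter below, 2925 carried the file's own name. No genome build was used here, so no gene coordinates are given.

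Background was corrected with limma's neqc, which fits the normexp model to background values inferred from the detection p-values, adds an offset of 16, takes log2 and applies quantile normalization. A probe was kept when its detection p lay under 0.05 on at least 4 arrays, the size of the smallest group, which left 21126 probes. Where several probes named a gene, the probe with the highest mean log2 value over all arrays was used, which left 14422 genes. Between 15342 and 17892 probes were detected per array. The number of arrays limits the precision of every value. Replicate arrays correlated at 0.964 to 0.995 over genes, and the smallest root-mean-square difference between replicate arrays was 0.236 on the log2 scale, so no array appeared to be present more than once.

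A linear model with a mean for each of the 8 groups was fitted to all 36 arrays with limma's lmFit and eBayes, with 28 residual degrees of freedom and 3.95 prior degrees of freedom. From it came 11 comparisons. They were the CD effect in wt and dko cells with and without crystals, the crystal effect in each genotype without CD, the genotype difference in untreated cells, the genotype difference of each CD effect and of the crystal effect, and the difference of the CD effect between loaded and unloaded wt cells. Genotype differences are given as dko minus wt. Calls were made at a Benjamini-Hochberg adjusted p under 0.05 by limma's moderated test, which is two-sided. Changes are on the log2 scale with their standard error (SE), and levels are mean normalized log2 intensity with the standard deviation (SD). All adjusted p-values for genes come from limma.

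Before the data were examined, 23 gene lists were fixed, together with the groups, the tests, the alternatives and the rule for the genes to be named. The pathway lists covered LXR target genes, cholesterol synthesis and uptake (targets of SREBP2), fatty acid synthesis and desaturation, cholesterol storage and transport, the NF-kB inflammatory response, the inflammasome, interferon-stimulated genes, the lysosome, the unfolded protein and integrated stress response, the NRF2 oxidative stress response, immediate early genes, the cell cycle, hypoxia and glycolysis, alternative activation and macrophage identity. The others were housekeeping genes and markers of T cells, B cells, neutrophils and granules, dendritic cells, stromal cells, erythroid and mast cells, and osteoclasts. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over 253 pairs of list and comparison. Of these, 58 were called, and 20 of the 58 were also called when the correlation was estimated from the residuals. Named genes were the targeted genes, the 8 called genes with the largest rise and the 8 with the largest fall (5 and 5 for the crystal effects and for differences of effects), without predicted or clone-named genes, and up to 4 members of each list with the smallest adjusted p. Every measured member of the LXR and cholesterol synthesis lists could also be named. Values of some genes that this rule takes are not reported here, while all counts and list tests include them.

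Alternatives were no normexp correction, normexp with an offset of 50, cyclic loess, median scaling, the series matrix values, no detection filter, a detection p under 0.01 on at least 18 arrays, each probe tested apart, a fit to the compared groups alone, the slide or the replicate number as a block, replicates 4 to 9 alone, array weights, a change of at least 1 on the log2 scale, and leaving out each array in turn. For lists, an estimated correlation and fry were also run. The replicate numbers were compared by the correlation over genes of the arrays' deviations from their group means. Every pair of same-numbered arrays correlated above 0.1, at 0.48 to 0.70, between the wt groups with crystals with and without CD. The blocked count is therefore given beside that comparison. In wt the replicate numbers coincide with the slides, as given below, so these correlations alone do not show pairs.

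The arrays lay on 6 slides. Replicates 1 to 3 of wt, 12 arrays, lay on 2 slides that held wt alone, and replicates 4 and 5 of wt, 8 arrays, shared 4 slides with all 16 dko arrays. Signal for Xist, an RNA made in female cells, lay above a log2 level of 7, a threshold set after the values were seen, on the 12 wt arrays of replicates 1 to 3, on 0 of the 8 wt arrays of replicates 4 and 5, and on 8 of the 16 dko arrays. In wt, the part of the slides, replicates 1 to 3 against 4 and 5, and Xist signal therefore coincide. A single replicate number did not follow a single slide. Effects in wt were computed within each part of the slides, and a block on the Xist signal was added after the data had been seen. In the shared part no slide held both a wt array with CD and its control of the same loading. CD effects in that part, with 2 arrays per group, may thus in part be slide differences. Xist signal was equally frequent in all groups of a genotype. Its block therefore left treatment changes within a genotype as they were and altered only their errors. On the 2 slides that held wt alone, crystal loading without CD largely followed the slide. Crystals replicates 2 and 3 and untreated replicate 1 lay on 1 slide, and crystals replicate 1 and untreated replicates 2 and 3 on the other. The pipeline was tested on simulated data with independent normal noise for each gene, in which 200 of 14422 genes, drawn at random, were changed. The lysosome list was also shifted by 0.5. The simulation held no slide or Xist structure and no correlation between genes, so recovery in the real data can be lower, above all for genes with a large spread. For the CD effect in loaded wt cells it recovered 34% of the changed genes at a log2 change of 0.5, 89% at 1 and 99% at 2. For the genotype difference of that effect it recovered 2.5%, 61.5% and 92.5%. R 4.3.3 was used with limma 3.58.1 and version 1.17.8 of data.table.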

Results

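Transcript levels were measured on 36 arrays of mouse bone marrow macrophages in 8 groups, formed by genotype (wt or LXRα/LXRβ dko), cholesterol crystals for 3 h and CD at 10 mM for 4 h. Each wt group held 5 arrays and each dko group 4. The study asked whether CD changes macrophage gene expression through the liver X receptors, nuclear receptors that sense oxidised cholesterol and switch on genes of cholesterol export. Array medians ran from 83.5 to 128 intensity units before normalization, and 14422 genes were tested.

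The targeted genes were Nr1h3, which encodes LXRα, and Nr1h2, which encodes LXRβ. The Nr1h3 probe read 9.46 ± 0.29 in untreated wt cells (log2 level, SD, n = 5) and 9.75 ± 0.14 in untreated dko cells (n = 4), a difference of 0.29 (SE 0.22, adjusted p = 0.615). The Nr1h2 probe read 8.83 ± 0.33 in wt and 9.30 ± 0.14 in dko, a difference of 0.47 (SE 0.25, adjusted p = 0.453). Of the other probes of these genes, 1 for Nr1h3 (detected on 34 of 36 arrays) and 1 for Nr1h2 (36 of 36) were higher in untreated dko cells by 0.58 and 0.64, and 1 for Nr1h2 was detected on 0 arrays. Where the probes lie relative to the deleted exons is not given in the sources used here, and a probe outside the deleted part checks nothing. The genotype labels are thus unchecked by these genes. Nr1h3 rose by 0.96 with CD in loaded dko cells (SE 0.23, adjusted p = 0.0272), while its CD effect in loaded wt cells was 0.65 (SE 0.21, adjusted p = 0.337).

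Crystal loading without CD showed how wt cells respond to the crystals, with no other particle as a control. The LXR target Abcg1, an exporter of cholesterol to HDL, went from 7.70 ± 0.17 to 10.69 ± 0.37 (n = 5 each), a rise of 2.99 (SE 0.26, adjusted p = 1.6e-09). Of the 21 measured LXR target genes 6 rose and 0 fell, among them Scd1, a fatty acid desaturase, by 1.57 (SE 0.26), Srebf1, a regulator of lipid synthesis, by 0.75 (SE 0.16), and Scd2 by 1.20 (SE 0.29). Abca1, a cholesterol exporter, rose as well, but was not above background on any untreated wt array, so its rise is given as at least 1.44-fold (adjusted p = 0.000289). This bound sets the mean of the loaded arrays against the lowest signal of detected probes on the untreated arrays. Genes of cholesterol synthesis and uptake fell in 14 of 24 cases and rose in 0, with Stard4, a sterol carrier, at -2.10 (SE 0.24), Cyp51, an enzyme of sterol synthesis, at -2.09 (SE 0.23), and Srebf2, the regulator of this pathway, at -1.17 (SE 0.13).

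Stress genes rose in the same loaded wt cells. Of 19 unfolded protein and integrated stress response genes 8 rose and 0 fell, with Trib3 up by 3.25 (SE 0.29), the stress transcription factor Ddit3 by 2.90 (SE 0.19) and Chac1 by 2.89 (SE 0.41). Of 16 NRF2 genes 7 rose and 0 fell, with the cystine transporter Slc7a11 (detected on 4 of 5 untreated arrays) up by 3.27 (SE 0.64) and the glutathione transferase Gsta3 by 2.95 (SE 0.33). Of 24 lysosome genes 9 rose and 0 fell, led by Ctsz at 1.19 (SE 0.18) and the proton pump subunit Atp6v1h at 1.15 (SE 0.14). Among other named genes, Gdf15 rose by 4.36 (SE 0.56), Kit, 1 of 4 erythroid and mast cell markers measured and detected on 2 of 5 untreated wt arrays, by 3.83 (SE 0.25), Tent5c by 3.56 (SE 0.26) and Acod1, which makes itaconate, by 3.46 (SE 0.75). Cytip changed by -2.77 (SE 0.42) and the chemokine receptor Cx3cr1 by -2.17 (SE 0.59).

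Over all genes, limma called 2019 for crystals in wt, 994 up and 1025 down, and for 1984 of these all 5 loaded arrays lay on the same side of the untreated mean. Counts of arrays on the changed side, here and below, are over genes called on the same arrays, so they are no separate evidence. With median scaling the call was 498 genes, 317 up and 181 down, and with the series matrix values 129, 95 up and 34 down. The list medians were -0.90 for cholesterol synthesis (camera adjusted p = 2.3e-16), 0.52 for the stress response (1.8e-09), 0.55 for NRF2 (7.1e-08) and 0.19 for the lysosome (4e-06), and all of these were also called with an estimated correlation. The LXR list, with a median of 0.18 (adjusted p = 0.00227), was not, with adjusted p = 0.0885 with an estimated correlation. Of 13 fatty acid genes 3 rose and 3 fell, 4 and 3 when adjusted over the list alone, and that list was not called, with a median of 0.02 (adjusted p = 0.828). When adjusted over the list alone, 6 LXR genes rose and 18 cholesterol synthesis genes fell. In the slides that held wt alone 2408 genes were called, and in the slides shared with dko 88. In the first of these parts loading largely followed the slide, so its values may in part be a slide difference. The LXR list median was 0.25 and 0.08 in these parts, the cholesterol synthesis median -0.98 and -0.72, the fatty acid median 0.09 and -0.0044, the stress response median 0.60 and 0.47, the NRF2 median 0.84 and 0.19, the lysosome median 0.21 and 0.22, and the Abcg1 change 3.12 and 2.79. Scd1 was called in both parts. In the shared slides alone Srebf1 (1.04 and 0.33), Scd2 (1.26 and 1.12) and Abca1 were not called, with adjusted p = 0.952, 0.362 and 0.427. With the slide as a block 1996 genes were called.

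In dko cells crystals lowered cholesterol synthesis genes as well, while no LXR target gene rose. Of 24 cholesterol synthesis genes 13 fell and 0 rose, with Stard4 at -1.79 (SE 0.27), Cyp51 at -1.70 (SE 0.26), Fdps at -1.68 (SE 0.25) and Srebf2 at -1.25 (SE 0.15). Of 21 LXR target genes 0 rose and 2 fell, the desaturase Scd2 at -1.47 (SE 0.33) and the acyl-CoA synthetase Acsl3 at -1.05 (SE 0.18). Abcg1 stood at 8.71 ± 0.20 without and 8.89 ± 0.07 with crystals (n = 4 each), a change of 0.18 (SE 0.29, adjusted p = 0.999). Kit, detected on 1 of 4 untreated dko arrays, rose by 2.42 (SE 0.28), Trib3 by 1.79 (SE 0.32), Tent5c by 1.70 (SE 0.29) and Ddit3 by 1.5 (SE 0.21). In all, limma called 60 genes, 34 up and 26 down, and in each of the 60 all 4 loaded arrays lay on the changed side of the untreated mean.

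The dko list medians were -1.0 for cholesterol synthesis (camera adjusted p = 4.6e-41), -0.36 for fatty acid synthesis (4.1e-08), 0.36 for the stress response (1.4e-07) and 0.15 for the lysosome (1.1e-05), each also called with an estimated correlation. Adjusted over the list alone, 19 cholesterol synthesis genes, 7 fatty acid genes, 5 stress genes and 6 lysosome genes were called. The LXR median was -0.14 (adjusted p = 0.00227, and adjusted p = 0.0885 with an estimated correlation), with 3 genes down when adjusted over the list alone. The NRF2 median was 0.23 (adjusted p = 0.000109, and adjusted p = 0.136 with an estimated correlation). With the slide as a block 107 genes were called, with median scaling 10, 3 up and 7 down, and with the series matrix values 3, all down. Within the 2 slides that held both groups the cholesterol synthesis median lay between -1.18 and -1.12 and the LXR median between -0.25 and -0.19.

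The crystal effect differed between genotypes in 6 genes, all with a lower effect in dko. They included Abcg1 at -2.81 (SE 0.39, adjusted p = 0.000448), Scd2 at -2.67 (SE 0.44, adjusted p = 0.00361), Scd1 at -2.12 (SE 0.39, adjusted p = 0.0137), Eepd1 at -2.10 (SE 0.32, adjusted p = 0.00206) and Gramd1b, a cholesterol transfer protein, at -1.36 (SE 0.25, adjusted p = 0.0122). The LXR list as a whole shifted by a median of -0.46 (camera adjusted p = 2.5e-13, and adjusted p = 0.00012 with an estimated correlation), with 3 genes called and 7 adjusted over the list alone. The fatty acid list shifted by -0.28 (adjusted p = 8.7e-07) with 2 genes called and 4 adjusted over the list alone, and the stress response list by -0.27 (adjusted p = 1.8e-05) with 0 called and 2 adjusted over the list alone, and both were also called with an estimated correlation. The 2 called fatty acid genes, Scd1 and Scd2, are also among the 3 called LXR genes, so the LXR and fatty acid lists are not separate results. With replicates 4 to 9 alone, median scaling and the series matrix values limma called 0 genes, with 254, 262 and 34 at an unadjusted p under 0.05. The changes of the named genes kept their direction there. With replicates 4 to 9, which hold 2 wt arrays per group, Abcg1 was at -2.61 (SE 0.50, adjusted p = 0.515), Scd2 at -2.59 (SE 0.56, adjusted p = 0.567), Scd1 at -2.34 (SE 0.48, adjusted p = 0.515) and Eepd1 at -1.32 (SE 0.35). With median scaling Abcg1 was at -2.81 (SE 0.57, adjusted p = 0.177), and with the series matrix values Abcg1 was at -2.44 (SE 0.51) and Scd2 at -1.24 (SE 0.37). With the slide as a block 5 were called. With replicates 4 to 9 alone the LXR median was -0.30 and the stress response median -0.17, both still called.

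**Figure D1:**
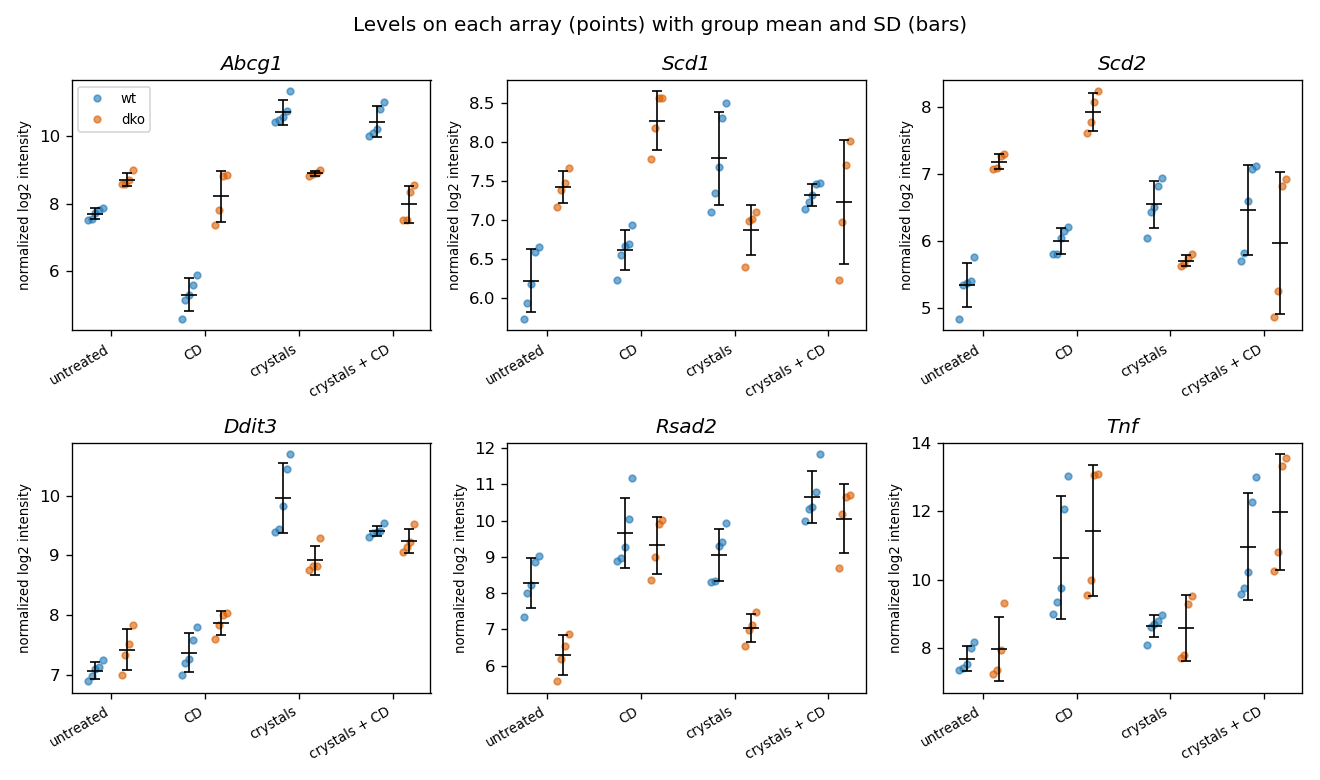
Normalized log2 intensity of 6 genes on each array (points) in the 4 treatments, for wt (blue, n = 5 each) and dko (orange, n = 4 each), with group mean and SD as bars. Abcg1 stands at 10.69 in loaded wt and at 8.89 in loaded dko cells.

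CD in unloaded wt cells raised cholesterol synthesis and inflammatory genes and lowered Abcg1. Of 24 cholesterol synthesis genes 13 rose and 0 fell, with Mvd, an enzyme of the mevalonate pathway, up by 1.79 (SE 0.21), Hsd17b7 by 1.49 (SE 0.20), Acat2 by 1.43 (SE 0.19) and Sqle by 1.31 (SE 0.18). Of 13 fatty acid genes 2 rose, Elovl6 by 1.20 (SE 0.23) and Fads2, detected on 3 of 5 untreated arrays, by 0.61 (SE 0.15). Of 21 LXR target genes 0 rose and 2 fell, Abcg1 from 7.70 ± 0.17 to 5.31 ± 0.49, a change of -2.39 (SE 0.26, adjusted p = 1e-06) with detection on 4 of 5 CD arrays, and Mertk, a receptor for dying cells, by -1.44 (SE 0.30).

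Of 22 NF-kB genes 5 rose with CD in unloaded wt cells and 0 fell, with the chemokine Cxcl10 up by 2.65 (SE 0.63), Cd40 by 2.62 (SE 0.55), the adhesion molecule Icam1 by 1.85 (SE 0.40) and the NF-kB subunit Relb by 1.14 (SE 0.22). Acod1 rose by 3.89 (SE 0.75), Cd69 by 3.52 (SE 0.81), Mycl by 2.89 (SE 0.57) and Gdf15 by 2.23 (SE 0.56). Cytip changed by -2.14 (SE 0.42), the growth factor Vegfa by -1.75 (SE 0.29) and Notch4 by -1.29 (SE 0.22). In the stress list 1 of 19 genes rose, Herpud1 by 1.29 (SE 0.27), and among 22 interferon-stimulated genes 1 rose, Cxcl10.

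For this comparison limma called 127 genes, 92 up and 35 down, and in 126 of them all 5 CD arrays lay on the changed side of the untreated mean. Median scaling called 26, 22 up and 4 down, and the series matrix values 9, all up. The cholesterol synthesis median was 0.99 (camera adjusted p = 5.5e-39, and adjusted p = 3.1e-05 with an estimated correlation) and the fatty acid median 0.31 (adjusted p = 0.000228, and adjusted p = 0.0471 with an estimated correlation). The NF-kB median of 1.64 (adjusted p = 2e-20) had adjusted p = 0.0943 with an estimated correlation, the interferon median of 0.42 (adjusted p = 1.5e-07) had adjusted p = 0.36 with an estimated correlation, and the stress median of 0.07 (adjusted p = 0.0434) had adjusted p = 0.304 with an estimated correlation. The LXR median was -0.02 (adjusted p = 0.335). Adjusted over the list alone, 19 cholesterol synthesis, 3 fatty acid, 15 NF-kB and 2 interferon genes rose and 3 LXR genes fell. In the slides with wt alone 46 genes were called and in the shared slides 251. In these parts the NF-kB median was 0.62 and 2.75, the interferon median 0.30 and 0.87, the cholesterol synthesis median 0.89 and 1.27, and the Abcg1 change -2.29 and -2.54. No shared slide held both groups, so the values there may in part be a slide difference. With the slide as a block 166 genes were called.

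CD in unloaded dko cells raised inflammatory, interferon-stimulated and cholesterol synthesis genes. Of 22 NF-kB genes 9 rose and 0 fell, with Cxcl10 (detected on 1 of 4 untreated arrays) up by 3.56 (SE 0.71), Ccl5 by 3.30 (SE 0.63) and Tnf by 3.46 (SE 0.88). Of 22 interferon-stimulated genes 9 rose and 0 fell, with the antiviral gene Rsad2 going from 6.29 ± 0.56 to 9.32 ± 0.78 (n = 4 each) and Gbp2 up by 2.81 (SE 0.54). Of 24 cholesterol synthesis genes 5 rose and 0 fell, with Mvd up by 1.42 (SE 0.24), Acat2 by 1.34 (SE 0.22) and Lss by 1.04 (SE 0.24). Acod1 rose by 4.34 (SE 0.84), Cd69 (detected on 3 of 4 untreated arrays) by 3.97 (SE 0.90) and the inflammasome gene Casp4 by 1.73 (SE 0.39). Cytip changed by -2.73 (SE 0.47), the thrombomodulin gene Thbd (detected on 3 of 4 CD arrays) by -1.64 (SE 0.33), Vegfa by -1.55 (SE 0.33) and Mertk by -1.38 (SE 0.33).

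Here limma called 250 genes, 165 up and 85 down, with all 4 CD arrays on the changed side of the untreated mean in each. Median scaling called 34, 32 up and 2 down, and with the series matrix values limma called 0, with 384 at an unadjusted p under 0.05. The cholesterol synthesis median was 0.61 (camera adjusted p = 1.9e-16, and adjusted p = 0.00623 with an estimated correlation). The NF-kB median was 2.06 (adjusted p = 7.4e-24, and adjusted p = 0.0702 with an estimated correlation), the interferon median 0.89 (1.3e-18, and adjusted p = 0.0719 with an estimated correlation), the fatty acid median 0.30 (0.00162, and adjusted p = 0.0885 with an estimated correlation) and the inflammasome median 0.18 (0.0145, and adjusted p = 0.188 with an estimated correlation). The LXR median was -0.10 (adjusted p = 0.773), with Mertk the 1 gene that fell and 0 that rose. Adjusted over the list alone, 19 NF-kB, 12 interferon, 14 cholesterol synthesis and 4 fatty acid genes rose. With the slide as a block 255 genes were called. Within the 2 slides that held both groups the NF-kB median was 1.0 and 3.23, the interferon median 0.51 and 1.23, and the cholesterol synthesis median 0.63 and 0.71.

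In crystal-loaded wt cells, the comparison closest to the question, CD changed no gene past the threshold in the main fit, which has no block. Abcg1 stood at 10.41 ± 0.45 with CD against 10.69 ± 0.37 without (n = 5 each), a difference of -0.28 (SE 0.26, adjusted p = 0.933). Scd1 differed by -0.47 (SE 0.26, adjusted p = 0.769). Abca1 differed by 0.05 (SE 0.16), at low levels of 5.25 with CD and 5.20 without, which limits the change its probe can show. Among inflammatory genes Cxcl10 differed by 2.39 (SE 0.63, adjusted p = 0.171), Tnf by 2.33 (SE 0.78, adjusted p = 0.363) and Relb by 1.03 (SE 0.22, adjusted p = 0.0686). Among interferon-stimulated genes Rsad2 differed by 1.61 (SE 0.44, adjusted p = 0.213) and Cmpk2 by 1.40 (SE 0.36, adjusted p = 0.149). Mvd, of cholesterol synthesis, differed by -0.40 (SE 0.21).

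The tool limma called 0 genes in loaded wt cells, with 1045 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0539. In wt the replicate number coincides with slide and Xist signal, so the correlation of same-numbered arrays does not by itself show pairs. With the replicate number as a block, 50 genes were called, 36 up and 14 down, and the block changed no list call. Of these, chosen for naming after their values were seen, Vegfa changed by -1.28 (SE 0.20, adjusted p = 0.00513), Nfkbie, an inhibitor of NF-kB, by 2.06 (SE 0.34, adjusted p = 0.0114) and Ifit3 by 1.36 (SE 0.24, adjusted p = 0.0114). Relb (SE 0.22, adjusted p = 0.0395) and Cmpk2 (SE 0.26, adjusted p = 0.0163) were also among the 50, at the changes given above, while Cxcl10, Tnf and Rsad2 were not. Without the block 4 lists were called as higher with the preset correlation and none of them with an estimated one, and no single gene passed over all genes. The interferon median was 0.79 (camera adjusted p = 1.1e-19, and adjusted p = 0.0634 with an estimated correlation) with 15 of 22 genes up when adjusted over the list alone. The NF-kB median was 1.16 (1.6e-14, and adjusted p = 0.197 with an estimated correlation) with 9 of 22. The inflammasome median was 0.20 (0.0211, and adjusted p = 0.216 with an estimated correlation) and the immediate early median 0.16 (0.0417, and adjusted p = 0.136 with an estimated correlation). The LXR median was -0.13 (adjusted p = 0.0932) with 0 genes passing, and the cholesterol synthesis median -0.05 (adjusted p = 0.78). In the slides with wt alone 4 genes were called, in the shared slides 63, with the slide as a block 6 and with the Xist signal as a block 162. In the parts with wt alone and shared with dko the NF-kB median was 0.41 and 2.47, the interferon median 0.62 and 1.20 and the LXR median -0.09 and -0.30. No shared slide held both groups, so the values of the shared part may in part be a slide difference. The LXR list was called as lower with the slide as a block, at -0.20 (camera adjusted p = 0.0142).

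In crystal-loaded dko cells CD raised interferon-stimulated and inflammatory genes. Of 22 interferon-stimulated genes 10 rose and 0 fell, with Gbp2 up by 3.06 (SE 0.54), Rsad2 by 3.03 (SE 0.50), Cmpk2 by 2.35 (SE 0.40) and Ifit3 by 2.26 (SE 0.43). Of 22 NF-kB genes 7 rose and 0 fell, with Tnf up by 3.41 (SE 0.88), Ccl5 by 3.12 (SE 0.63), Icam1 by 2.55 (SE 0.44) and Relb by 1.39 (SE 0.25). Of 14 inflammasome genes 1 rose, Casp4 by 1.76 (SE 0.39). The receptor Fpr2 rose by 3.28 (SE 0.87), Acod1 by 3.33 (SE 0.84) and Cd40 by 2.98 (SE 0.62). Lpar6 changed by -2.10 (SE 0.55), Cytip by -1.92 (SE 0.47), Mertk by -1.44 (SE 0.33) and Vegfa by -1.34 (SE 0.33). Of 21 LXR target genes 0 rose and 1, Mertk, fell.

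In this comparison limma called 261 genes, 184 up and 77 down, and in 259 of them all 4 CD arrays lay on the changed side. Median scaling called 2, both up, and with the series matrix values limma called 0, with 322 at an unadjusted p under 0.05. The interferon median was 1.33 (camera adjusted p = 8.2e-27, and adjusted p = 0.024 with an estimated correlation) and the NF-kB median 2.02 (2.1e-21, and adjusted p = 0.0885 with an estimated correlation). The inflammasome median was 0.23 (0.000423, and adjusted p = 0.0585 with an estimated correlation) and the LXR median -0.17 (0.0391, and adjusted p = 0.263 with an estimated correlation). For 18 interferon, 15 NF-kB and 4 inflammasome genes a rise passed when adjusted over the list alone. With the slide as a block 357 genes were called, and within the 3 slides that held both groups the NF-kB median lay between 0.44 and 3.20 and the interferon median between 0.65 and 1.68. Leaving out replicate 8 of the loaded dko arrays with CD gave 33 genes.

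**Figure D2:**
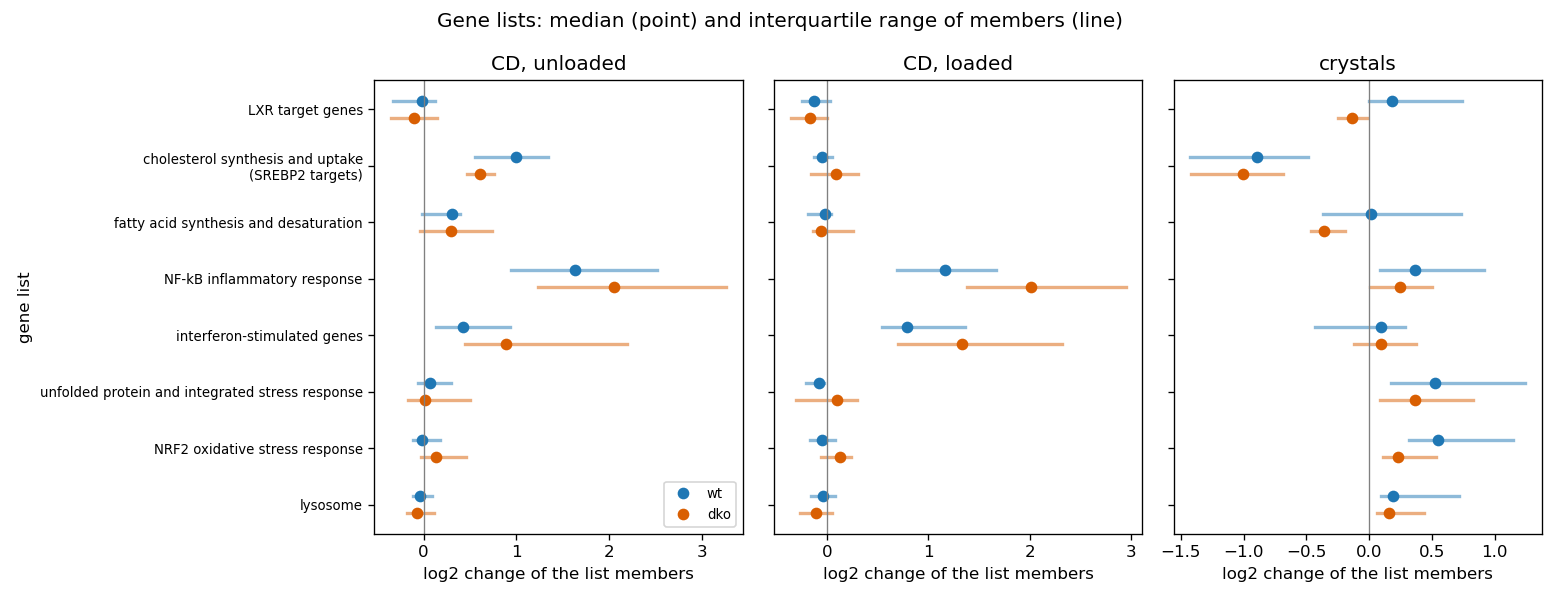
Median log2 change (point) and interquartile range of the members (line) of 8 gene lists for CD without crystals, CD with crystals and crystals alone, in wt (blue) and dko (orange). The LXR list lies at -0.13 for CD in loaded wt cells and at 0.18 for crystals in wt.

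The CD effect was compared between genotypes directly. In loaded cells limma called 0 genes, with 313 at an unadjusted p under 0.05. In unloaded cells it called 0, with 246. The Abcg1 effect in unloaded cells was higher by 1.89 in dko (SE 0.39, adjusted p = 0.388, detected on 4 of 5 unloaded wt arrays with CD), and in loaded cells it differed by -0.63 (SE 0.39, adjusted p = 1). The LXR list median differed by -0.04 in loaded cells (adjusted p = 0.552). The interferon list differed by 0.56 in loaded and 0.55 in unloaded cells (camera adjusted p = 1.4e-06 and 1.6e-09, and adjusted p = 0.413 and 0.263 with an estimated correlation). The NF-kB list differed by 0.69 and 0.48 (1.1e-05 and 0.00172, and adjusted p = 0.579 and 0.758 with an estimated correlation), and with replicates 4 to 9 alone these turned to -0.39 and -0.59. The interferon differences were then 0.17 and 0.13 and no longer called (camera adjusted p = 0.589 and 0.0812). In these replicates no slide held both a wt array with CD and its control of the same loading, so slide differences may enter. In loaded cells the macrophage identity list differed by -0.17 (0.0221, and adjusted p = 0.217 with an estimated correlation). In unloaded cells the cholesterol synthesis list differed by -0.37 (0.000123, and adjusted p = 0.239 with an estimated correlation) and the NRF2 list by 0.18 (0.0215, and adjusted p = 0.417 with an estimated correlation). With replicates 4 to 9 alone the macrophage identity and NRF2 differences were not called (-0.06 and 0.09, adjusted p = 0.808 and 0.522).

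Across genes, which are not independent replicates, the CD effects of the genotypes were set side by side, with no arrays in common. Over the 127 genes called in unloaded wt cells, the changes in dko correlated with those in wt at r = 0.956 with a slope of 0.982 (dko on wt), and over the 250 genes called in unloaded dko cells r was 0.95 with a slope of 0.71 (wt on dko) and 246 had the same sign. Of these 127 genes, 80 were also called in dko, all with the same sign, where independent lists would share 2.20. Over the 261 genes called in loaded dko cells, r was 0.952, 259 had the same sign in wt, and the slope of wt on dko was 0.562. Over the 2019 genes called for crystals in wt, the slope of dko on wt was 0.472, and over the 60 called in dko that of wt on dko was 1.18 (r = 0.932), with 57 of the same sign. Each slope was taken over genes chosen for their change in 1 genotype, which pulls the slope of the other on it down. A slope below 1 thus does not by itself show a weaker effect. Over all 14422 genes r was lower, at 0.791 for CD in unloaded cells, 0.715 for CD in loaded cells and 0.751 for crystals. For crystals 55 genes were called in both genotypes, 54 with the same sign.

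**Figure D3:**
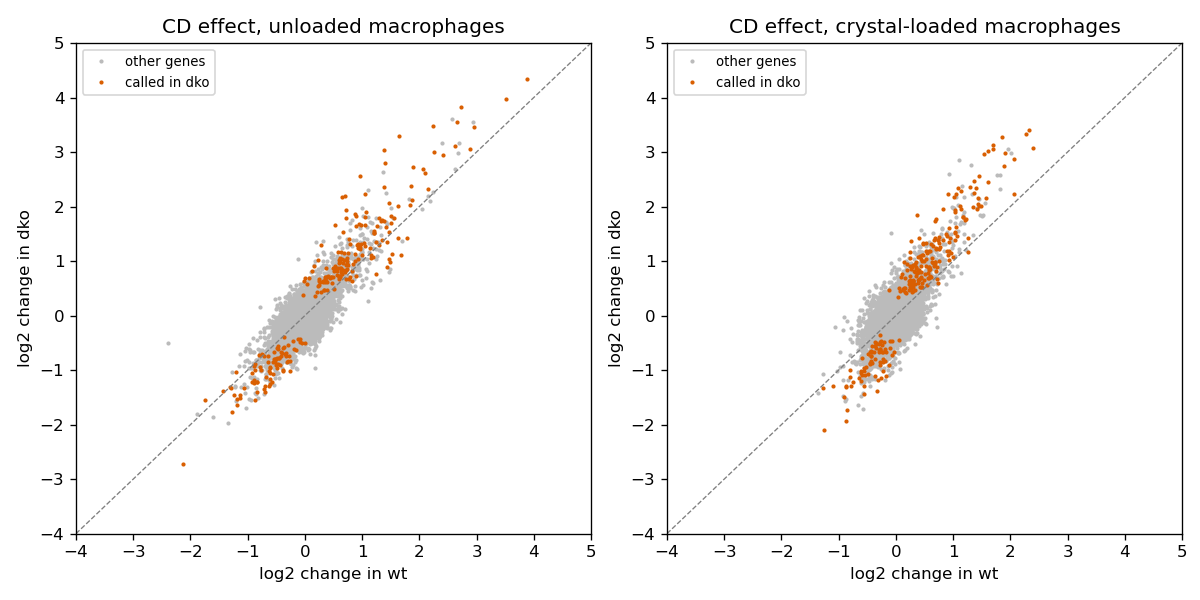
Log2 change with CD of each gene in wt (horizontal axis) and dko (vertical axis), in unloaded (left) and crystal-loaded (right) cells, with genes called in dko in orange and equal change as a dashed line. In loaded cells 259 of the 261 called genes lie on the same side of 0 in both genotypes.

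The CD effect in wt cells differed between loaded and unloaded cells in 10 genes, 1 with a higher and 9 with a lower effect in loaded cells. Abcg1 was the higher, at 2.11 (SE 0.36, adjusted p = 0.00582), with detection on 4 of 5 unloaded CD arrays. Mvd was lower at -2.19 (SE 0.30, adjusted p = 0.000362), Lss at -1.58 (SE 0.30, adjusted p = 0.0211) and Aacs at -1.44 (SE 0.21, adjusted p = 0.000659). The cholesterol synthesis list shifted by a median of -1.06 (camera adjusted p = 2.9e-46, and adjusted p = 1.8e-05 with an estimated correlation), with 4 of 24 genes called and 18 when adjusted over the list alone. The fatty acid list shifted by -0.36 (5.5e-06) and the stress list by -0.24 (0.000109), both also called with an estimated correlation. The interferon list shifted by 0.29 (0.00535, and adjusted p = 0.747 with an estimated correlation) and the cell cycle list by 0.13 (0.0348, and adjusted p = 0.582 with an estimated correlation). With median scaling and the series matrix values limma called 0 genes, with 196 and 34 at an unadjusted p under 0.05, and replicates 4 to 9 alone called 1. Abcg1 was at 2.06 (SE 0.53) with median scaling, 1.07 (SE 0.48) with the series matrix values and 2.14 (SE 0.58) with replicates 4 to 9, and Mvd at -2.14 (SE 0.38), -1.37 (SE 0.31) and -2.25 (SE 0.45), none of these called.

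Untreated dko cells differed from untreated wt cells in 30 genes, 16 higher and 14 lower, each with all 4 dko arrays on the same side of the wt mean. Scd2 was higher by 1.83 (SE 0.31), Aig1, a lipid hydrolase detected on 4 of 5 wt arrays, by 1.72 (SE 0.22), Gsta3 by 1.65 (SE 0.35), and the sterol synthesis genes Lss and Fdps by 1.18 (SE 0.23) and 1.13 (SE 0.23). Gpd2, the mitochondrial glycerol phosphate dehydrogenase, was lower, at 5.59 ± 0.28 in dko against 8.24 ± 0.40 in wt (n = 4 and 5, adjusted p = 4.3e-05). The interferon-stimulated genes Ifit3 and Oasl2 differed by -2.04 (SE 0.41) and -1.56 (SE 0.33), and the nucleotide reductase subunit Rrm2 by -1.03 (SE 0.20). Of 21 LXR target genes 1, Scd2, was higher and 0 lower, and Abcg1 differed by 1.01 (SE 0.27, adjusted p = 0.107).

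Several lists shifted between the untreated genotypes. The cell cycle median was -0.38 (camera adjusted p = 1.8e-09, and adjusted p = 0.0428 with an estimated correlation) and the fatty acid median 0.34 (1.8e-05, and adjusted p = 0.0216 with an estimated correlation). The cholesterol synthesis median was 0.45 (1.6e-08, and adjusted p = 0.0634 with an estimated correlation), the interferon median -0.66 (1.5e-12, and adjusted p = 0.174 with an estimated correlation), the LXR median 0.05 (0.0166, and adjusted p = 0.188 with an estimated correlation) and the inflammasome median -0.26 (0.0182, and adjusted p = 0.198 with an estimated correlation). Adjusted over the list alone, 7 cell cycle and 10 interferon genes were lower, and 4 fatty acid, 11 cholesterol synthesis and 6 LXR genes were called. Among lists of markers of other cells, those of stromal cells and neutrophils were called with the preset correlation and not with an estimated one. The stromal median was 1.25 (1.9e-08, and adjusted p = 0.0885 with an estimated correlation) with 0 of 10 genes passing over all genes and 9 adjusted over the list alone, and the neutrophil and granule median was 0.54 (0.0189, and adjusted p = 0.383 with an estimated correlation).

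In this genotype comparison the slide as a block gave 96 genes, 17 of the 30 among them, and replicates 4 to 9 alone 63, while median scaling gave 2 genes, 1 up and 1 down, and the series matrix values 1, down. These scalings moved the median of all genes by -0.14 and -0.24, against at most 0.03 in size for quantile normalization, so small differences between the genotypes are relative to the scaling. Within the 1 slide that held both untreated groups the cholesterol synthesis median was 0.56, the interferon median -0.34, the cell cycle median -0.04, the fatty acid median 0.28, the LXR median 0.19 and the stromal median 0.07, with 1 array of each genotype. With replicates 4 to 9 alone the interferon median was -0.24 and the stromal median 0.75, both still called, and the LXR, inflammasome and neutrophil lists were not called (adjusted p = 0.16, 0.357 and 0.092).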

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

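The tests of exchanged arrays and the counts over other splits of the arrays were chosen after the results they bear on had been seen.

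The crystal effect without CD differed between the genotypes in 6 genes, by limma's test of the difference itself. In the same comparison the median of the LXR target list differed by -0.46, that of the fatty acid list by -0.28 and that of the unfolded protein and integrated stress response list by -0.27 (dko minus wt). The LXR and fatty acid lists share members, Scd1 and Scd2 among them. The CD effect in wt differed between loaded and unloaded cells in 10 genes. There the median of the cholesterol synthesis list differed by -1.06, that of the fatty acid list by -0.36 and that of the stress list by -0.24 (loaded minus unloaded).

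In 5 of 112 groups of values tested, 1 array stood far from the others of its group, against about 1 in 20 by chance. Nr1h3 read 9.96 on replicate 6 of untreated dko cells, where the others read 9.67 to 9.70. It read 10.28 on replicate 6 of dko cells with CD, where the others read 10.51 to 10.55. In dko cells with crystals, replicate 6 read 4.40 for Abca1, detected on 3 of these 4 arrays, against 4.75 to 4.81, and 6.40 for Scd1 against 6.99 to 7.11. Ddit3 read 9.29 on replicate 9 of the same group, against 8.75 to 8.83.

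In dko, arrays with 1 replicate number differed in Xist signal. Exchanging a loaded with an unloaded dko array would put that pair in the reverse order, where the score follows the treatment. The score was taken over the genes called for crystals in wt, with a limit set at 49 of 64 pairs. The loaded array was higher in 64 of 64. For CD, scored on the genes called in unloaded wt cells, 64 of 64 pairs were also in the labelled order, which argues against exchanged treatment labels within dko. Eif2s3y, a gene of the Y chromosome, read 8.94 to 9.74 on dko arrays without Xist signal and 4.18 to 4.60 on those with it. Each dko number thus held arrays of both sexes and, as labelled, cannot stand for 1 animal. Whether arrays were exchanged within a treatment group, and what the numbers stand for, stays open. No biological explanation was tested.

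Other splits of the same arrays were counted for each comparison, all in limma. This count argued against chance for crystals in wt (2019 genes, highest other split 724, 1 of 100 splits as large with the real one). It did so too for the untreated genotypes (30, highest other 19, 1 of 100). In both, 100 of 126 possible splits were counted, so chance is not excluded. For the genotype difference of the crystal effect the share was also under 0.05 (6, highest other 508, 4 of 100) though 3 other splits called at least as many. The LXR list, fixed before the data were examined, differed there by -0.46 (adjusted p = 0.00012 with an estimated correlation). The splits alone did not exclude chance for CD in unloaded wt cells (127, highest other 422, 5 of 100), CD in loaded dko cells (261, highest other 1422, 2 of 35), CD in unloaded dko cells (250, highest other 1589, 2 of 35), crystals in dko (60, highest other 736, 2 of 35) and the loading difference of the CD effect (10, highest other 1595, 7 of 100). For the first 4 of these, the calls were set beside arrays of the other genotype, none of them shared. In each of the 4, a list fixed before was also called with an estimated correlation, as given above. Genes that vary together are not independent, so the overlaps below do not by themselves exclude chance. Of the 127 genes in unloaded wt cells 80 were also called in dko, all with the same sign, where independent lists would share 2.20. Of the 261 genes in loaded dko cells 259 had the same sign in wt, and of the 60 for crystals in dko 55 were also called in wt, 54 with the same sign, where independent lists would share 8.40. For the loading difference the cholesterol synthesis list, also fixed before, argues against chance, with adjusted p = 1.8e-05 with an estimated correlation. In the slides with wt alone and in the shared slides, which have no arrays in common, its median change with CD was 0.89 and 1.27 without crystals and 0.04 and -0.18 with crystals. With wt alone, all loaded arrays with CD lay on 1 slide and all unloaded ones with CD on the other. No shared slide held both a wt array with CD and its control of the same loading. Slide differences may thus enter in both parts. With 0 genes called, 100 of 100 splits were as large for CD in loaded wt cells (highest other 17) and for the genotype differences of the CD effect in loaded (highest other 1095) and unloaded cells (highest other 823), where limma gave 1045, 313 and 246 genes at an unadjusted p under 0.05. With the replicate block, CD in loaded wt cells called 50 genes and the highest other split that parts all 5 pairs 0, and its 16 splits are too few for a share under 0.05, the real one being 1 of them.

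Splits that called several times the real count point to a structure of the arrays other than treatment. For the CD effects and for crystals in dko, the highest other split put all 4 arrays without Xist signal on 1 side. In wt that split follows the parts of the slides. The CD effect in the part with wt alone and in the shared part gave 46 and 251 genes without crystals. With crystals it gave 4 and 63. No shared slide held both wt groups of either comparison, so a slide difference may add to the shared counts. Xist signal was equally frequent in all groups of a genotype, so a block on it alters the errors of treatment changes and not the changes. The median of all genes for CD in loaded wt cells was -0.0135 with and without it. With the Xist signal as a block, 162 genes were called for CD in loaded wt cells, 459 in unloaded wt cells, 862 in loaded dko cells, 858 in unloaded dko cells and 283 for crystals in dko. All 127, 261, 250 and 60 genes called without that block in the last 4 were among them. Of the 30 genes that differed between the untreated genotypes, 20 were kept among the 145 called with that block.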

How the results depend on the processing

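The Xist block, the values within parts of the slides and the correlation over genes called in loaded dko cells were chosen after the data had been seen. All other alternatives were planned. Counts below are genes called by limma, and unless a reason is given the cause was not tested.

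CD in loaded wt cells called 0 genes, 3 without normexp, 3 with normexp at offset 50, 9 with cyclic loess, 6 with the stricter detection filter, 6 with the slide as a block, 33 with replicates 4 to 9, 50 with the replicate block, 19 with array weights and 162 with the Xist block. CD in unloaded wt cells called 127, against 26 with median scaling, 9 with the series matrix, 76 without a filter, 64 with the compared groups alone, 235 with the replicate block, 459 with the Xist block and 58 at a change of at least 1. CD in loaded dko cells called 261, against 2 with median scaling, 0 with the series matrix, 135 without a filter, 154 with the compared groups alone, 465 with replicates 4 to 9, 434 with the replicate block, 1493 with array weights, 862 with the Xist block and 120 at a change of at least 1. CD in unloaded dko cells called 250, against 34, 0, 115 (compared groups alone), 477 (replicates 4 to 9), 441 (replicate block), 490 (weights), 858 (Xist block) and 126 (at least 1), the first values being median scaling and the series matrix.

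Crystals in wt called 2019, against 498 with median scaling, 129 with the series matrix, 80 with replicates 4 to 9, 3055 with the Xist block and 422 at a change of at least 1. Crystals in dko called 60, against 10 with median scaling, 3 with the series matrix, 160 with the compared groups alone, 107 with the slide block, 207 with replicates 4 to 9, 140 with the replicate block, 339 with weights, 283 with the Xist block and 32 at a change of at least 1. The untreated genotypes differed in 30, against 2 with median scaling, 1 with the series matrix, 15 with the compared groups alone, 96 with the slide block, 63 with replicates 4 to 9, 314 with weights, 145 with the Xist block and 14 at a change of at least 1. The genotype difference of the CD effect in unloaded cells went from 0 to 1 with the Xist block. That of the crystal effect went from 6 to 0 with median scaling, 0 with the series matrix, 0 with replicates 4 to 9, 10 with weights and 18 with the Xist block. The loading difference went from 10 to 0 with median scaling, 0 with the series matrix, 1 with replicates 4 to 9 and 18 with the Xist block. The fit to replicates 4 to 9 held fewer wt arrays, and the threshold of 1 removes genes by construction. With replicates 4 to 9 no slide held both a wt array with CD and its control of the same loading. The series matrix moved the median of all genes by 0.15 in the genotype difference of the CD effect in unloaded cells and by 0.14 in the loading difference.

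Calls of lists fell from 58 to 20 with an estimated correlation. The LXR list for CD in loaded wt cells (-0.13) was called as lower with median scaling (-0.14, adjusted p = 0.0334), the series matrix (-0.029, 0.00187), the slide block (-0.20, 0.0142) and replicates 4 to 9 (-0.30, 0.0286). For crystals in wt it lost its call with an estimated correlation (0.18, 0.0885). The NF-kB list turned with replicates 4 to 9 in the genotype difference of the CD effect in loaded (-0.39, adjusted p = 0.159) and unloaded cells (-0.59, adjusted p = 0.0134). The correlation over genes called in loaded dko cells went from 0.952 to 0.901 with weights. It was not computed under median scaling and the series matrix, and that over genes called in unloaded wt cells not under the series matrix, for too few genes. The cholesterol synthesis median for CD in unloaded wt cells and the LXR median in the genotype difference of the crystal effect kept their direction and call under every alternative run other than leaving out arrays, over 0.562 to 1.27 and -0.474 to -0.167, and the correlation over genes called in unloaded wt cells ran from 0.915 to 0.979. Of 4721 values of named genes under alternatives 839 lost the call, 17 gained it and 0 turned, and of 6815 for lists 183 lost it and 173 gained it.

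Of the pairs of groups set against each other for a treatment, CD in loaded wt cells was the 1 where every pair of same-numbered arrays correlated above 0.1. Every pair did so too between wt cells with CD and wt cells with crystals and CD (0.564 to 0.721, 5 of 5 best with their own number) or crystals alone (0.359 to 0.575, 4 of 5). Between the first 2 groups no same-numbered arrays shared a slide, so a shared slide does not account for those correlations. The lowest correlation was 0.05 for CD in unloaded wt cells, -0.024 for crystals in wt, -0.44 and -0.49 for CD in loaded and unloaded dko cells and -0.51 for crystals in dko, and 2 of 5, 2 of 5, 1 of 4, 2 of 4 and 0 of 4 arrays correlated best with their own number. The replicate block kept 127 of 127 calls for CD in unloaded wt cells, 257 of 261 in loaded and 249 of 250 in unloaded dko cells, 1993 of 2019 for crystals in wt and 60 of 60 in dko, and moved no count by over 1.5 times beyond those given above. In dko each number held arrays with and without Xist signal, so the block there does not stand for animals. Same-numbered dko arrays with CD and with crystals and CD correlated at -0.724 to -0.530.

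Leaving out each array in turn gave 0 to 37 genes for CD in loaded wt cells, 45 to 181 in unloaded wt cells, 33 to 444 in loaded dko cells, 55 to 425 in unloaded dko cells, 1498 to 2003 for crystals in wt, 35 to 90 in dko, 8 to 73 for the untreated genotypes, 0 to 0 and 0 to 1 for the genotype difference of the CD effect in loaded and unloaded cells, 4 to 10 for that of the crystal effect and 6 to 12 for the loading difference. List calls ran from 52 to 64. The LXR median ran from -0.225 to -0.0539 for CD in loaded wt cells, from 0.120 to 0.261 for crystals in wt and from -0.546 to -0.346 in the genotype difference, the cholesterol synthesis median from 0.888 to 1.08, and the correlations from 0.917 to 0.966 and from 0.926 to 0.960.

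Single arrays that moved a count by over 1.5 times were, for CD in loaded wt cells, crystals and CD replicates 1 (37) and 3 (1) and crystals replicate 2 (5), and the LXR list was called as lower without crystals and CD replicate 3 (-0.22), crystals replicate 1 (-0.13) or 2 (-0.05). For unloaded wt cells they were CD replicates 4 (56) and 5 (45) and untreated 1 (77) and 3 (70). For loaded dko cells they were crystals and CD 6 (41), 7 (444) and 8 (33) and crystals 6 (67), 7 (90), 8 (125) and 9 (133). For unloaded dko cells they were CD 6 (425), 7 (82) and 9 (55) and untreated 6 (136), 7 (101) and 8 (131). For crystals in dko they were crystals 7 (36) and untreated 8 (35). For the untreated genotypes they were dko 6 (8), 8 (68) and 9 (8) and wt 1 (17), 2 (13), 3 (12), 4 (73) and 5 (62). For the differences of effects they were dko CD 9 (1), wt crystals 5 (10), and, with 6 genes each in the loading difference, crystals and CD 2, CD 4, CD 5 and untreated 2 and 3. Signal over background limits low genes, such as Abca1, which was not detected in unloaded wt cells and was low in loaded ones.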

Other observations

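The tests below were chosen after the results they bear on had been seen, except the test of chromosomes 2 and 7.

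Crystal loading of wt cells also changed genes of other groups. Of 21 cell cycle genes 9 fell and 0 rose, with Rrm2 at -0.73 (SE 0.19), Cdk1, the mitotic kinase, at -0.56 (SE 0.13) and Mcm5 at -0.54 (SE 0.15), and the list median was -0.42 (camera adjusted p = 0.000306, and adjusted p = 0.263 with an estimated correlation). Of these genes 11 fell when adjusted over the list alone. Of 14 inflammasome genes 3 fell, Txnip at -1.31 (SE 0.28), Il18 at -0.91 (SE 0.15) and Nlrc4 at -0.81 (SE 0.19), with a list median of -0.16 (0.037, and adjusted p = 0.263 with an estimated correlation). Of 16 macrophage identity genes 5 fell and 0 rose, among them Cd14 at -1.13 (SE 0.28), Fcgr3 at -1.10 (SE 0.23) and Itgam at -0.87 (SE 0.21), though the list was not called (median -0.16, adjusted p = 0.119). Of 13 hypoxia and glycolysis genes 4 rose and 1 fell, with Pgam1 up by 1.05 (SE 0.18) and the glucose transporter Slc2a1 by 0.75 (SE 0.20) while Pdk1 was at -0.79 (SE 0.18), and the list median was 0.18 (0.0313, and adjusted p = 0.138 with an estimated correlation). Among 15 immediate early genes 2 rose and 2 fell, Egr2 by 1.73 (SE 0.36) and Fos at -1.26 (SE 0.19) among them, and the list was not called, with a median of -0.11 against a mean of 0.03 (adjusted p = 0.828). In the slides with wt alone and in the shared slides the cell cycle median was -0.54 and -0.29, the inflammasome median -0.29 and -0.12 and the hypoxia and glycolysis median 0.28 and 0.07, and with replicates 4 to 9 alone the last 2 lists were not called (adjusted p = 0.103 and 0.151). Of 22 NF-kB genes 1 rose, the interleukin 1 antagonist Il1rn by 2.44 (SE 0.29).

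Of the 23 lists, 8 were called in none of the 11 comparisons. For crystals in wt the cholesterol storage and transport list had a median of -0.0024 with 2 of 16 genes down, Cyp27a1 at -1.03 (SE 0.28) and Scp2 at -0.43 (SE 0.10). In the same comparison the alternative activation list (9 measured) had a median of 0.03, the housekeeping list (10) 0.0013 with Hprt at -0.31 (SE 0.11), the B cell list (4) -0.05, the osteoclast list (7) -0.025 against a mean of 0.04, with Dcstamp at -0.71 (SE 0.24), and the dendritic cell list (5) 0.08 against a mean of -0.07, with H2-DMb2 at -0.74 (SE 0.18). The T cell list (4) had a median of 0.0041 and a mean of 0.48, with Cd28 up by 1.96 (SE 0.27), and the erythroid and mast cell list (4) a median of -0.02 and a mean of 0.90, with Kit, detected on 2 of 5 untreated arrays, up by 3.83 (SE 0.25). With CD, Cd28 changed by -1.31 (SE 0.30) in loaded dko cells and Osbpl3, of the oxysterol-binding protein family, by 1.46 (SE 0.35). In the genotype difference of the crystal effect the NRF2 list shifted by -0.31 (camera adjusted p = 0.000109, and adjusted p = 0.136 with an estimated correlation), the cell cycle list by 0.28 (0.000401, and adjusted p = 0.269 with an estimated correlation) and the lysosome list by -0.12 (0.0182, and adjusted p = 0.155 with an estimated correlation). With replicates 4 to 9 alone, whose wt arrays lie on the slides shared with dko, the NRF2 and lysosome lists were not called (-0.02 and -0.03, adjusted p = 0.808 and 0.408), the NRF2 median for crystals in wt being 0.19 there, 0.84 in the slides with wt alone and 0.23 in dko.

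The LXR target list did not rise with CD in loaded wt cells. Probes unable to register a rise are argued against by the 6 of 21 list members that rose with crystals in wt. A ceiling of the array signal after loading is argued against by the brightest of these, Abcg1, which lay 4.00 log2 units below the brightest gene of the same arrays. A limit of single probes was not tested. Whether LXR genotype changes the CD effect on the list stays open, since the test of the difference gave adjusted p = 0.853 with an estimated correlation at a median difference of -0.04, which does not show that the genotypes act alike.

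Untreated dko and wt cells differed in 30 genes, and DNA of another strain around the targeted loci may contribute to such differences. Of 25 of these genes with a chromosome, 3 lay on chromosomes 2 and 7, which per the array table hold Nr1h3 and Nr1h2, against 16.2% of all tested genes (12%, exact Clopper-Pearson interval 2.55 to 31.2, one-sided Fisher's exact p = 0.794). The share lay below that of all genes but by less than its interval. The test counted whole chromosomes without gene coordinates, so it says little about DNA close to the loci. Strain DNA at the 3 genes there, Gpd2 on chromosome 2 among them, stays open, while 22 genes lay elsewhere. More stromal cells in the dko cultures could also contribute, since the median of the 10 stromal markers, 1 of which (Thy1) is also a T cell marker, differed by 1.25, with Col1a1 at 9.03 in dko against 7.11 in wt, Sparc at 9.45 against 7.52, Col6a1 at 10.40 against 8.05 and Dcn at 10.49 against 9.18, while within the 1 slide that held both untreated groups, with 1 array of each, the median was 0.07. With adjusted p = 0.0885 with an estimated correlation this and a change of these genes within macrophages cannot be told apart, and slide and sex of the animals also stay open.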
